A study of Mus musculus with 16 samples.

How the data were processed

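RNA from growing mouse oocytes was measured on 16 Affymetrix arrays of the Mouse 1.1 ST design, which reads each transcript with several short probes summarised as a probe set. Per the labels, 4 genotypes were sampled with 4 biological replicates each: wild type, Hdac1 knockout, Hdac2 knockout and knockout of both genes. Each sample pooled 80 oocytes from mice 12 days old, and the series' design text names a small-sample RNA kit and a whole-transcriptome amplification step before biotin labelling.

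The deposited table holds 1 value per probe set and array, 35556 probe sets in all, with no missing value. These deposited values are on a log scale taken as log2, running from 2.07 to 12.89. The labels do not state the base, so it was inferred from the values: with base e the highest value would stand for a brightness of 394439, beyond the 65536 steps of a 16-bit scanner, and with base 2 it stands for 7566. Processing that rescales the values could take them past the scanner's range, so this does not settle the base. All fold changes printed rest on that inference. MAS5 is named per the submitters' processing notes, with its version not given, and the series' design text names MAS5, GeneSpring v7, SAM and EASE with a limit of 1.4-fold. How those programs were combined to make the deposited values is not given in the sources used here. Array medians lay between 4.46 and 4.59, and the largest distance of an array's quartile from the median over arrays was 0.103, inside the limit of 0.2 set for renormalizing, so the values were used as deposited.

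Probe sets were named through the platform's annotation table. Exactly 1 gene symbol was given for 21218 probe sets, several symbols for 1881 and none for 12457. The 21218 with 1 symbol were tested, covering 18820 genes, of which 1386 had more than 1 probe set; a gene named in the text is represented by its probe set with the highest mean over the 16 arrays, and probe sets that differ are named. By gene identifier 21185 of these probe sets matched the supplied RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table was used for chromosome and gene order alone, and no coordinates are printed because the files name no genome build.

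One linear model with a mean per genotype was fitted to all 16 arrays in R 4.3.3 with limma 3.58.1 (lmFit, contrasts, eBayes; 12 residual degrees of freedom), and p-values were two-sided and adjusted by the Benjamini-Hochberg method over the probe sets tested. A probe set was counted as changed at an adjusted p under 0.05. The 7 contrasts were each knockout against wild type, the double knockout against each single knockout, the single knockouts against each other, and the interaction, which is the departure of the double knockout from the sum of the single-knockout changes on the log2 scale. Standard errors are limma's, and SDs are over the 4 arrays of a group. For Hdac1 and Hdac2, a two-sided exact permutation test over the 70 arrangements of 4 against 4 arrays was added, whose smallest possible p is 0.0286.

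Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with a correlation estimated from the residuals, adjusted over the lists within a contrast. The 24 lists were histone deacetylases and sirtuins, subunits of HDAC1/2 complexes, histone acetyltransferases, H3K4 methyltransferase complexes, H3K4 demethylases, DNA methylation machinery, core histone genes, p53 targets, cyclin-dependent kinase inhibitors, pro-apoptotic genes, anti-apoptotic genes, oocyte growth genes, oocyte maturation and maternal dormant mRNA genes, meiotic prophase genes, piRNA pathway genes, 2-cell stage genes, REST-repressed neuronal genes, RNA polymerase II and general factors, the unfolded protein and integrated stress response, ribosomal protein genes, oxidative phosphorylation genes, and markers of granulosa cells, of theca and stroma, and of blood, immune and endothelial cells. The marker lists cover cells of the ovary that could accompany isolated oocytes.

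The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule took Hdac1 and Hdac2, then for each comparison with wild type up to 10 higher and 10 lower genes with the largest change among those that passed, had all 4 knockout arrays beyond all 4 wild-type arrays, exceeded the median of tested probe sets in the higher group and had no provisional symbol. It added up to 4 members of each list with the smallest adjusted p in the double knockout, and up to 5 higher and 5 lower genes for each other contrast, where the interaction did not need separated arrays. Genes named outside the rule are said to be chosen after their values were seen.

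Overlaps between comparisons that share the 4 wild-type arrays were set against 20 simulations of unchanged groups, against independent lists, and against the 6 divisions of the wild-type arrays into separate controls. Calls among the 50 genes on either side of Hdac1 and Hdac2 were compared with all other tested probe sets by Fisher's exact test. Alternatives tried were quantile normalization, median-centring, a filter on dim probe sets, the replicate number as a block, a fit of the compared groups alone, eBayes with trend and robust, a SAM-type statistic with 1.4-fold, the 1.4-fold limit alone, all probe sets, and leaving out each array in turn. In a test on simulated data for the double knockout against wild type, run on 21218 probe sets, limma recovered 41 of 50 probe sets changed by 0.5 on the log2 scale and 50 of 50 at each of 1, 2 and 4, with 13 false calls; camera called the list shifted by 0.5 and 1 other list.

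The number of arrays limits the precision. An array value has no count behind it, and a floor of signal holds dim probe sets near the lower end of the scale above their true level, so their changes in either direction are understated.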

Results

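Gene expression was compared in oocytes from 12-day-old mice lacking the histone deacetylases Hdac1, Hdac2 or both, enzymes that remove acetyl groups from histones and act in shared co-repressor complexes. Deletion used conditional alleles and a Cre transgene under the Zp3 promoter, which is active in growing oocytes, and the stated question was what the 2 enzymes do during oocyte growth. Each genotype had 4 arrays of 80 pooled oocytes. Within a genotype, the arrays correlated across probe sets at 0.992 to 0.995, and double-knockout arrays correlated with wild-type arrays at 0.972 to 0.977. The main axis of a principal component analysis held 64.2% of the variance and set the 4 double-knockout arrays (49.2 to 55.6) apart from the 12 others (all below 0).

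Hdac1 (probe set 10516605) averaged 9.28 ± 0.05 (SD, n = 4) on the log2 scale in wild type and 6.61 ± 0.19 in the Hdac1 knockout, where it fell by 2.66 and 15.8% of the wild-type signal was left. In the double knockout it stood at 7.66 ± 0.10 and fell by 1.62, with 32.5% of the signal left, and it was 2.06-fold higher there than in the Hdac1 knockout. In the Hdac2 knockout Hdac1 rose 1.29-fold to 9.64 ± 0.11. The limma adjusted p was 3.97e-12, 2.38e-10 and 0.0172 for the Hdac1, double and Hdac2 knockouts against wild type and 5.22e-08 between the double and Hdac1 knockouts, and each of these 4 differences had the smallest p of the exact permutation test (0.0286). The other Hdac1 probe set changed by -2.71, -1.63 and 0.35 in the same knockouts. The rise in the Hdac2 knockout lost its call without Hdac2-knockout replicate 1 (limma adjusted p = 0.0533) or replicate 2 (0.0525).

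Hdac2 (probe set 10362520) was at 11.09 ± 0.07 in wild type, 11.13 ± 0.05 in the Hdac1 knockout, 10.99 ± 0.03 in the Hdac2 knockout and 10.87 ± 0.06 in the double knockout. It fell by 0.21 in the double knockout (limma adjusted p = 0.00274), while the difference of -0.10 in the Hdac2 knockout did not pass over all probe sets (limma adjusted p = 0.33; exact permutation p = 0.0286). With 93.5% of the wild-type signal left in the Hdac2 knockout, this probe set did not show the deletion. The deleted exons and those it reads are not given in the sources used here, and a probe set outside the deleted part checks nothing, so the Hdac2 genotype was left unchecked.

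**Figure D1:**
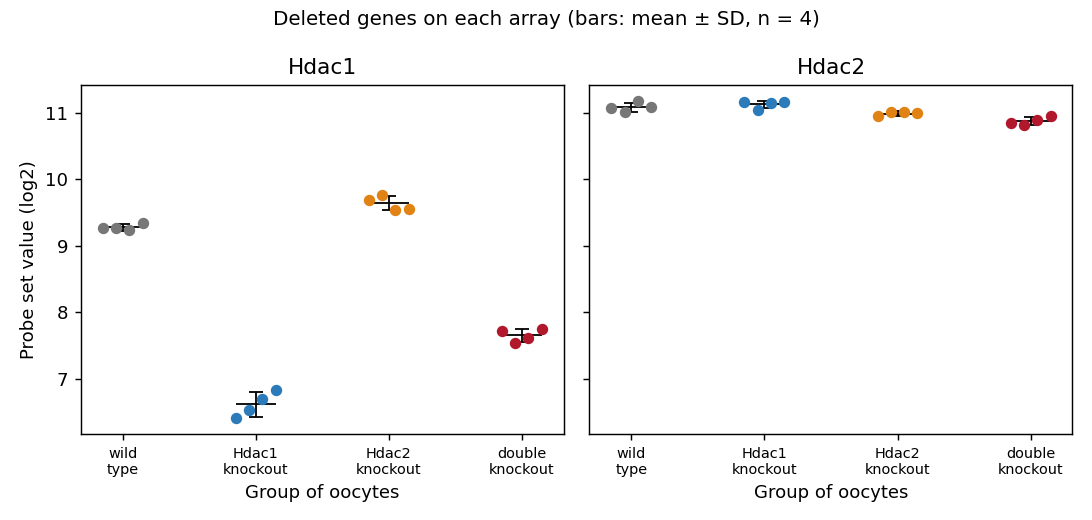
Probe set values (log2) of Hdac1 and Hdac2 on each of the 16 arrays, by group; black bars give the mean and SD of 4 arrays. Hdac1 averages 6.61 in the Hdac1 knockout and 7.66 in the double knockout against 9.28 in wild type, and the 4 group means of Hdac2 lie between 10.87 and 11.13.

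The Hdac1 knockout differed from wild type in 15 probe sets of 14 genes, 4 higher and 11 lower, 2 of them the probe sets of Hdac1. Mt1 (probe set 10574027), a metal-binding metallothionein, rose 24.8-fold from 6.51 ± 0.10 to 11.14 ± 0.21 (SD, n = 4). Ostm1, a partner of a lysosomal chloride transporter, rose 1.71-fold, and Dvl1, a transducer of Wnt signals, rose 1.36-fold. Rnase6, a secreted ribonuclease, fell by 4.19 ± 0.50 (SE) on the log2 scale, from 9.15 ± 0.09 to 4.96 ± 0.32. Smaller falls were those of Enpp3 (-0.93), Prep, a prolyl endopeptidase (-0.83), Slc6a20a, an imino acid transporter (-0.82), Poglut2 (-0.52), Dtwd2 (-0.41) and Wasf1, an actin regulator (-0.36). The limma adjusted p ran from 5.1e-15 for Mt1 to 0.0487 for Dvl1. Of the 13 calls outside Hdac1 itself, 5 lay on chromosome 10, which also carries Hdac2 and holds 4.64% of the tested probe sets; they were Ostm1, Enpp3, Prep, Wasf1 and Adgrg6, the last named after its values were seen. Ostm1, Enpp3, Prep and Wasf1 also set the Hdac1 knockout apart from both other knockouts, and in the double knockout Enpp3 and Wasf1 rose against wild type by 0.61 and 0.32 (limma adjusted p = 0.00113 and 2.35e-05). Without replicate 4 of the Hdac1 knockout 30 probe sets were called, and with dim probe sets left out 24 were. Calls for Dvl1, Dtwd2 and Adgrg6 were lost in 7, 5 and 2 of the 8 fits without 1 array.

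Among the lists, subunits of HDAC1/2 complexes were shifted upward in the Hdac1 knockout, with a median change of 0.05 (camera adjusted p = 0.0187; adjusted p = 0.581 with an estimated correlation). Of its 31 measured members 0 passed over all genes, and adjusted over the list alone 2 were higher and 0 lower. This call was lost without wild-type replicate 1 (0.0646) or Hdac1-knockout replicate 1 (0.0753), and other divisions of the same 8 arrays called up to 3 lists. In the other 23 lists, the deacetylase list had 1 lower member, Hdac1 itself, and no other member passed over all genes. Median, mean and test differed in sign for the deacetylases, cyclin-dependent kinase inhibitors, 2-cell stage genes, oxidative phosphorylation genes, core histones and the stress response, which were not called. Oxidative phosphorylation genes passed without wild-type replicate 3 (0.0341) and meiotic prophase genes without Hdac1-knockout replicate 4 (0.0372).

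The Hdac2 knockout differed from wild type in 1187 probe sets, 606 higher and 581 lower, which is 5.59% of those tested. Mt1 rose 23.4-fold to 11.06 ± 0.10 (SD, n = 4). Gpat3, an enzyme of triglyceride synthesis, rose 8.1-fold from 5.60 ± 0.04 to 8.61 ± 0.96, and Extl1, an exostosin-like glycosyltransferase, rose 6.01-fold from 4.44 ± 0.11 to 7.03 ± 0.25. The forkhead factor Foxa3 rose 4.26-fold, the nucleosome-binding protein Hmgn3 4.17-fold, the amino acid transporter Slc38a2 4.08-fold and the homeobox gene Hdx 4.03-fold. Gdf11, a ligand of the TGF-beta family, rose 3.47-fold, followed by Tceal8 (3.08-fold) and Smoc1 (3.07-fold). The standard errors of these log2 changes ran from 0.09 for Hmgn3 to 0.52 for Gpat3, and the limma adjusted p from 6.9e-15 for Mt1 to 0.00298 for Slc38a2.

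The genes that fell furthest in the Hdac2 knockout included Hivep2, a zinc finger factor (-1.50 ± 0.17 SE), Ednrb, an endothelin receptor (-1.44 ± 0.13), and Slc5a8, a monocarboxylate transporter (-1.27 ± 0.12). Mrc1, a mannose receptor, fell by 1.04, Pfkfb2, a regulator of glycolysis, by 1.03, Tktl2 by 1.02 and Slc15a5 by 0.99. Sgms1, a sphingomyelin synthase, fell by 1.64 ± 0.40 and Cpxm2 by 1.03 ± 0.26, and both calls were lost in 5 of the 8 fits without 1 array. Crybg1 fell by 1.06, while its other probe set changed by -0.06 (limma adjusted p = 0.815). The count of 1187 fell in all 8 fits without 1 array, which have fewer arrays in the test, to between 683 and 952. It was 770 and 722 without wild-type replicates 3 and 4, and 683 and 716 without Hdac2-knockout replicates 1 and 4. At 1.4-fold or more 454 remained under the same test. Which direction held the majority turned with the scaling, at 443 higher and 763 lower with each array centred on its median and 559 and 646 with quantile normalization.

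Of 31 measured subunits of HDAC1/2 complexes, 7 rose and 1 fell in the Hdac2 knockout, 23 did not pass, and adjusted over the list alone 9 were higher and 1 lower (median 0.07; camera adjusted p = 0.000975; adjusted p = 0.165 with an estimated correlation). One of them was Rcor3, a co-repressor of the CoREST complex, at 1.19-fold, a call lost in 7 of the 8 fits without 1 array. Among 8 H3K4 demethylases 2 rose and 6 did not pass, and adjusted over the list alone 2 were higher and 0 lower (median 0.11; camera adjusted p = 0.00634; adjusted p = 0.165 with an estimated correlation). They were Kdm5b, which rose 2.5-fold from 5.64 ± 0.32 to 6.96 ± 0.31 (limma adjusted p = 0.000369), and Kdm2b, 1.22-fold, chosen after its values were seen. Of 8 cyclin-dependent kinase inhibitors 1 rose, Cdkn1c at 1.59-fold, 7 did not pass, and adjusted over the list alone 3 were higher and 0 lower (median 0.14; camera adjusted p = 0.0138; adjusted p = 0.165 with an estimated correlation). That last call was lost with dim probe sets left out (0.174), and other divisions of these 8 arrays called up to 5 lists against the 3 found.

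The 21 other lists were not called in the Hdac2 knockout, though oxidative phosphorylation genes passed without replicate 1 of that group (0.025). Of the 2-cell stage genes 3 of 15 rose, 1 fell and 11 did not pass, and adjusted over the list alone the counts were 3 and 1 (camera adjusted p = 0.367); Usp17lb, a deubiquitinase, rose 1.46-fold, a call lost in 4 of the 8 fits without 1 array. Among single members, the H3K4 methyltransferase Kmt2a rose 1.66-fold and the pro-apoptotic gene Bcl2l11 1.25-fold, the latter lost in 2 of those 8 fits. Median, mean and test differed in sign for 7 of these lists: maturation genes, p53 targets, DNA methylation machinery, REST-repressed genes, polymerase II factors, theca and stroma markers and ribosomal proteins.

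Calls in the Hdac2 knockout gathered around Hdac1 on chromosome 4. Of 50 tested probe sets within 50 genes on either side of Hdac1, 9 were called (18%) against 5.56% of all others, 2 of the 9 being probe sets of Khdrbs1, chosen after its values were seen (Fisher's exact test, two-sided, adjusted p = 0.0097 over 6 tests). The corresponding counts were 0 of 50 in the Hdac1 knockout and 15 of 50 in the double knockout. Around Hdac2 they were 0 of 59, 2 of 59 and 22 of 59 in the Hdac1, Hdac2 and double knockouts, and none of these 5 other tests passed. Around Hdac2, a window of 100 genes passed in the Hdac1 knockout (2 of 98; adjusted p = 0.00478) and one of 20 genes in the double knockout (12 of 17; 0.0305). Across the genome, 108 calls set the Hdac2 knockout apart from all 3 other groups, and 31 of them lay on chromosome 4 (28.7% against 5.99% of tested probe sets), a count made after the values were seen; of all calls in this knockout 7.85% did (Fisher's exact test, adjusted p = 0.168). Of these 31, 6 lay within 50 genes of Hdac1, which itself rose in the Hdac2 knockout. The distance of the others from Hdac1 was not examined. Extl1, with the largest change among these 31, was at 4.55 ± 0.14 (SD, n = 4) in the double knockout and 4.61 ± 0.13 in the Hdac1 knockout.

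The double knockout differed from wild type in 8122 probe sets of 7358 genes, 38.3% of those tested, with 3924 higher and 4198 lower. The balance depended on the scaling, with 2895 higher and 6506 lower when each array was centred on its median and 3382 and 5025 with quantile normalization. At 4-fold or more, 183 were higher and 5 lower. Zfp352 (probe set 10505914), a zinc finger gene of the early embryo, rose 125-fold from 4.05 ± 0.21 to 11.02 ± 0.27 (SD, n = 4), Rfpl4b, of the ret finger protein-like family, 86.8-fold, and Tdpoz3, a TD and POZ domain gene, 70.4-fold. Cd24a, a surface glycoprotein, rose 46.6-fold, Tmem92 43.6-fold, the deubiquitinase Usp17lb 41.5-fold and Grp, which encodes gastrin-releasing peptide, 36.5-fold. Xkrx rose 34.9-fold, Tdpoz8 34.2-fold and Pramel17 32.6-fold. The standard errors of these log2 changes ran from 0.13 to 0.43, and the highest limma adjusted p among them was 2.77e-09. Wild-type values of these genes lay between 3.33 and 4.91, near the lower end of the scale, where folds are understated, and close copies in the Usp17l, Tdpoz and Pramel families share probe sequence.

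Mt1 rose 23.6-fold in the double knockout to 11.07 ± 0.07 (SD, n = 4), a level that differed from the Hdac1 knockout by -0.07 (limma adjusted p = 0.57). Among genes that fell, Ccdc149 went from 7.81 ± 0.09 to 5.69 ± 0.55 (-2.12 ± 0.19 SE), Qrfprl, a receptor gene, fell by 2.06, Tmem260 by 2.03 and the phosphatase Cdc14b by 1.92. The desmosomal cadherin Dsc2 fell by 1.81, the kinase gene Styk1 by 1.81, Hivep2 by 1.80, the GATA-type repressor Trps1 by 1.73 and the membrane glycoprotein Gpm6a by 1.73. Rnase6 fell by 2.33 ± 0.50, with double-knockout arrays spread over an SD of 1.54. The highest limma adjusted p among these falls was 0.00135, for Rnase6.

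**Figure D2:**
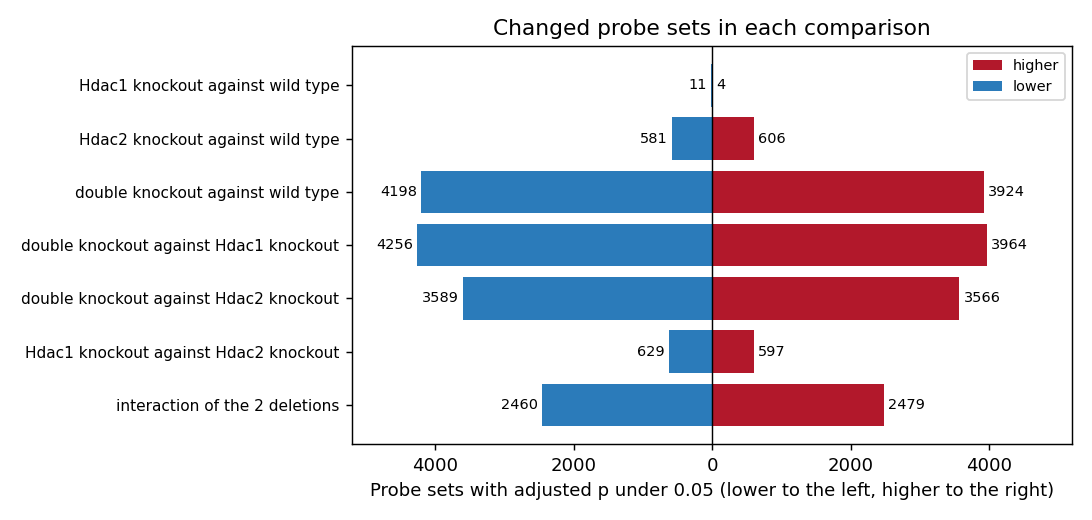
Number of probe sets that passed limma's test in each of the 7 comparisons, higher to the right and lower to the left. The double knockout has 3924 higher and 4198 lower against wild type, the Hdac2 knockout 606 and 581, and the Hdac1 knockout 4 and 11.

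Genes of the 2-cell embryo rose as a group in the double knockout. Of 15 measured, 10 rose, 2 fell and 3 did not pass, adjusted over the list alone 10 were higher and 2 lower, and the median change was 2.12 (camera adjusted p = 1.26e-06; adjusted p = 0.216 with an estimated correlation). Besides Zfp352, Tdpoz3, Tmem92 and Usp17lb, they included Usp17la, which rose 24.8-fold. The 2 that fell, chosen after their values were seen, were Zfp750 (-1.23 ± 0.12 SE) and Obox5 (-0.36 ± 0.06). Several of these genes are near copies, which a set test counts as separate members.

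Cyclin-dependent kinase inhibitors, which hold back cell-cycle kinases, rose in 7 of 8 cases, 0 fell and 1 did not pass; adjusted over the list alone 7 were higher and 0 lower, and the median was 0.66. Cdkn1c rose 3.23-fold, Cdkn3 2.77-fold, Cdkn1a 2.56-fold and Cdkn2c 1.79-fold (camera adjusted p = 3.93e-05; adjusted p = 0.0418 with an estimated correlation). It was the 1 list of the 8 called in this comparison that kept its call with an estimated correlation. Of 33 p53 targets 13 rose, 7 fell and 13 did not pass, with the same 13 and 7 adjusted over the list alone; the list was not called (median 0.07; camera adjusted p = 0.106), but passed at 0.0477 with each array centred on its median. Plk2, a polo-like kinase, rose 3.89-fold, Plk3 3.6-fold and the anti-proliferative gene Btg2 3.11-fold, while the DNA polymerase gene Polk fell by 1.16.

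Among 17 pro-apoptotic genes 3 rose, 4 fell and 10 did not pass, with 3 and 4 adjusted over the list alone (camera adjusted p = 0.719). Bcl2l11, which encodes Bim, rose 2.49-fold and Pmaip1, which encodes Noxa, 2.19-fold. The median of this list was -0.04, while its mean was 0.07 and its test pointed upward. Among 14 anti-apoptotic genes 2 rose, 5 fell and 7 did not pass, with 3 and 5 adjusted over the list alone (camera adjusted p = 0.719). Mcl1 rose 1.27-fold, and Bcl2l1 fell by 0.34.

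Chromatin genes moved in both directions in the double knockout. Of 31 subunits of HDAC1/2 complexes 15 rose, 4 fell and 12 did not pass, and adjusted over the list alone 15 were higher and 6 lower (median 0.14; camera adjusted p = 0.0186; adjusted p = 0.243 with an estimated correlation). Ing2, of the Sin3 complex, rose 3.05-fold, Mta2, of the NuRD complex, 2.16-fold, and Rcor3 1.44-fold, while Phf21a, of the CoREST complex, fell by 1.03. The dimmer second probe set of Mta2 changed by -0.08 (limma adjusted p = 0.577). Of 18 deacetylases and sirtuins 1 rose, 7 fell and 10 did not pass, and adjusted over the list alone 3 were higher and 7 lower (median -0.08; camera adjusted p = 0.265). Hdac8 fell by 0.98 and Sirt4 by 0.72, and Hdac5 rose 1.48-fold from a dim 3.80. Of 12 histone acetyltransferases 3 rose, 5 fell and 4 did not pass, and adjusted over the list alone 3 were higher and 6 lower (median -0.09; camera adjusted p = 0.265); Kat6b fell by 1.20 and Kat5 by 0.48.

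H3K4 demethylases, which remove methyl groups from histone H3, rose in 4 of 8 cases, 1 fell and 3 did not pass, with 4 and 1 adjusted over the list alone (median 0.15; camera adjusted p = 0.0356; adjusted p = 0.308 with an estimated correlation). Kdm5b rose 17.6-fold from 5.64 ± 0.32 to 9.77 ± 0.12 (SD, n = 4), and Riox1 rose 1.69-fold, which its other 2, dimmer probe sets did not. Kdm1b was the member that fell (-0.15), chosen after its values were seen and lost in 4 of the 8 fits without 1 array. The list call was lost without wild-type replicate 1 (0.0519), double-knockout replicate 1 (0.0608) or double-knockout replicate 4 (0.0503). Of 15 members of H3K4 methyltransferase complexes 3 rose, 4 fell and 8 did not pass, with 4 and 4 adjusted over the list alone (camera adjusted p = 0.76), and Kmt2a rose 3.04-fold.

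Of 13 genes of the DNA methylation machinery 3 rose, 5 fell and 5 did not pass, with 3 and 5 adjusted over the list alone (camera adjusted p = 0.912); the median was 0.03, but the mean was -0.10 and the test pointed downward. The methyltransferase Dnmt3b rose 1.67-fold, its cofactor Dnmt3l fell by 1.24, and Tet1, which oxidises methylcytosine, fell by 1.17 on a probe set that 2 dimmer ones did not match. Of 30 core histone genes 12 rose, 2 fell and 16 did not pass, and adjusted over the list alone 13 were higher and 2 lower (median 0.15; camera adjusted p = 0.0186; adjusted p = 0.321 with an estimated correlation). H2bc1 rose 2.22-fold and the variant gene H2az2 1.78-fold, and H2ac6 fell by 1.55.

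Oocyte growth genes were at high levels in wild type (median 11.32) and 29 of 42 did not pass in the double knockout; 2 rose and 11 fell, or 2 and 10 adjusted over the list alone (median -0.04; camera adjusted p = 0.467). Figla, a transcription factor for zona pellucida genes, fell by 0.56 and the RNA helicase gene Ddx4 by 0.32, and Sohlh1, a regulator of early follicles, rose 2.11-fold. Of 28 maturation and maternal dormant mRNA genes 5 rose, 12 fell and 11 did not pass, and adjusted over the list alone 7 were higher and 14 lower (median -0.16; camera adjusted p = 0.221). Pde3a, the phosphodiesterase that lowers cAMP before meiosis resumes, fell by 0.73 and Gpr3, a receptor that raises cAMP, by 0.69, while Cdc25b rose 2.4-fold and Cdc20 1.47-fold.

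Of 33 meiotic prophase genes 7 rose, 9 fell and 17 did not pass, with 7 and 9 adjusted over the list alone (camera adjusted p = 0.719); the median was -0.13 and the test pointed downward, but the mean was 0.04. Meioc, a meiosis-specific gene, rose 12.7-fold from 3.73 ± 0.12 to 7.39 ± 0.25 (SD, n = 4), the synaptonemal protein gene Sycp3 rose 1.58-fold and the mismatch repair gene Mlh3 fell by 0.84. Genes of the piRNA pathway, which silences transposons, fell in 13 of 21 cases, 4 rose and 4 did not pass, and adjusted over the list alone 14 were lower and 4 higher (median -0.33; camera adjusted p = 0.0336; adjusted p = 0.216 with an estimated correlation). Tdrd12 fell by 0.88 and Tdrd9 by 0.69, and Wdr77 rose 2.96-fold. The piRNA call was also lost with median-centring (0.0895) and with dim probe sets left out (0.142).

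Small shifts ran through the 2 largest lists. Of 75 oxidative phosphorylation genes 46 rose, 3 fell and 26 did not pass, and adjusted over the list alone 50 were higher and 3 lower (median 0.24; camera adjusted p = 7.19e-09; adjusted p = 0.321 with an estimated correlation). Cox7a1 rose 2.13-fold and Ndufa12 1.71-fold. Of 72 ribosomal protein genes 37 rose, 2 fell and 33 did not pass, and adjusted over the list alone 45 were higher and 2 lower (median 0.17; camera adjusted p = 1.74e-07; adjusted p = 0.419 with an estimated correlation). Rps19 rose 1.52-fold and Rpl9 1.46-fold, and all 7 other probe sets of Rpl9, whose sequence has many copies, changed by 0.55 to 0.73. Median-centring of each array lowered all changes in this comparison by 0.09, and both calls held.

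Of 50 RNA polymerase II and general factors 8 rose, 10 fell and 32 did not pass, with 8 and 10 adjusted over the list alone (camera adjusted p = 0.719). Polr2a, the largest polymerase subunit, rose 1.69-fold and the elongation kinase Cdk9 1.63-fold, and Gtf2e1 fell by 0.63. Of 26 genes of the unfolded protein and integrated stress response 8 rose, 5 fell and 13 did not pass, and adjusted over the list alone 8 were higher and 6 lower (camera adjusted p = 0.444). The stress factor Atf3 rose 6.29-fold and the chaperone gene Dnajb9 4.75-fold, and the cystine transporter Slc7a11 fell by 0.97. Of 36 neuronal genes repressed by REST 9 rose, 7 fell and 20 did not pass, and adjusted over the list alone 9 were higher and 9 lower (camera adjusted p = 0.66). The neurofilament gene Nefm rose 7.73-fold from 3.50 ± 0.07, and the secretogranin gene Scg3 fell by 0.64.

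None of the 3 lists of markers of other ovarian cells was called, though each had more members higher than lower. Of 22 granulosa cell markers 5 rose, 3 fell and 14 did not pass, with 5 and 3 adjusted over the list alone (median 0.01; camera adjusted p = 0.66); 3 of the 22 lay at or above the median of tested probe sets in wild type. Nr5a2, a nuclear receptor, fell by 1.07 and the connexin gene Gja1 rose 1.68-fold. Of 23 theca and stroma markers 4 rose, 2 fell and 17 did not pass, with 4 and 2 adjusted over the list alone (median 0.08; camera adjusted p = 0.444). The smooth muscle myosin gene Myh11 fell by 0.81, and fibronectin, Fn1, rose 2.61-fold from 4.35. Of 20 blood, immune and endothelial markers 5 rose, 3 fell and 12 did not pass, with 5 and 3 adjusted over the list alone (camera adjusted p = 0.66); the median was -0.02, but the mean was 0.13 and the test pointed upward. Flt1 rose 5.69-fold and the complement gene C1qb 2.33-fold, and Pecam1 fell by 1.37.

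**Figure D3:**
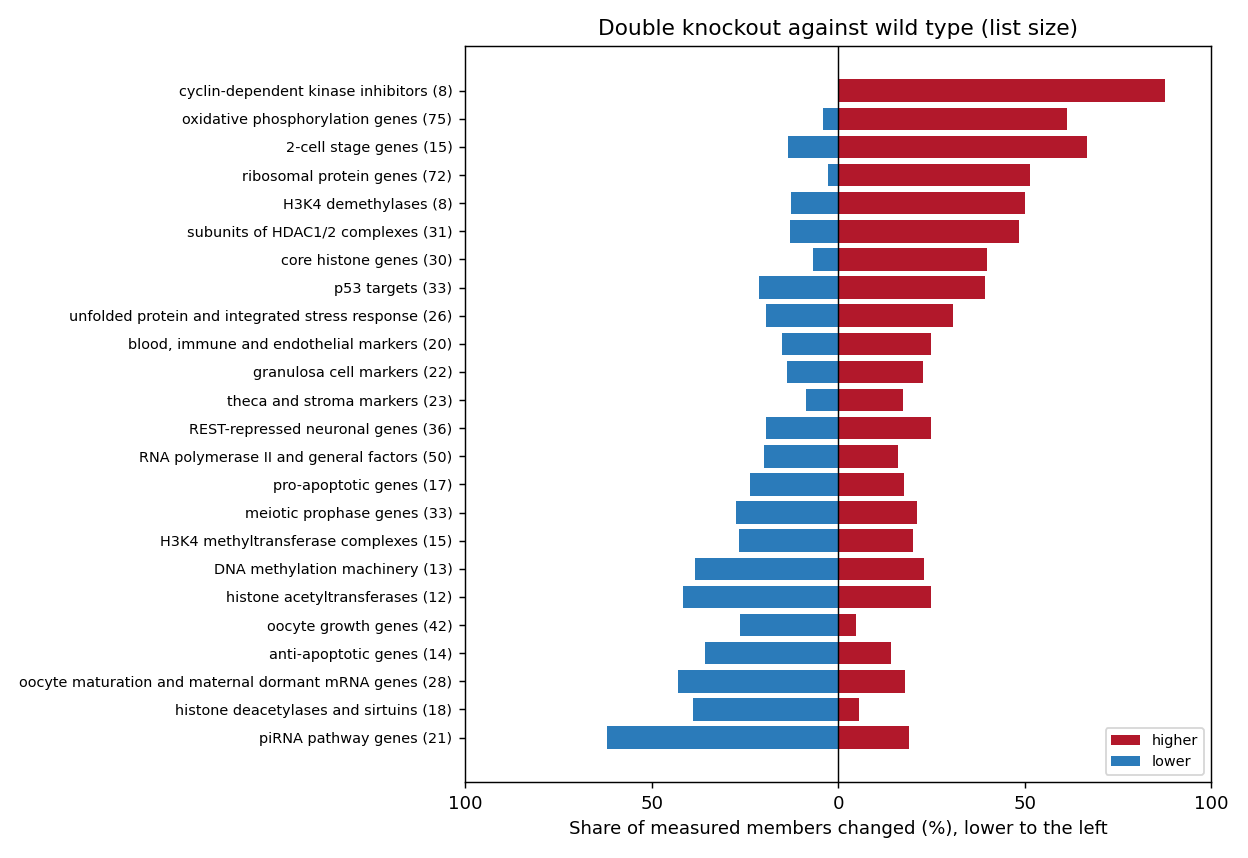
Share of each list's measured members (in %, list size in parentheses) that were higher or lower in the double knockout than in wild type by limma's test. Cyclin-dependent kinase inhibitors lead with 7 of 8 higher, and piRNA pathway genes have 13 of 21 lower.

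The Hdac2 and double knockouts shared 932 calls in the same direction, 468 higher and 464 lower, with 33 in opposite directions. Independent lists of these sizes would share 112.1 and 115 calls. Simulated groups with no changed probe set and common simulated controls shared 0. Such groups call almost nothing, so that 0 gives no chance level for lists of these sizes. With the wild-type arrays divided so that the comparisons shared none, the overlap averaged 336 over 6 divisions (299 to 396), but those fits had fewer control arrays and called 452 probe sets in the Hdac2 knockout on average, against 1187. The covariance of the log2 changes was 0.0476 against 0.00491 in the simulations, and the correlation across probe sets, which are not independent replicates, was 0.48 against 0.49. With divided controls the correlation averaged 0.40 and the covariance 0.0427 for this pair. The correlation then averaged 0.003 for the Hdac1 and double knockouts and 0.12 for the single knockouts. The Hdac1 and double knockouts shared 10 calls in the same direction, 2 of them the probe sets of Hdac1, with 2 in opposite directions. With divided controls 6 were shared on average, and 9.17 rather than 15 were called in the Hdac1 knockout. With shared controls the covariance was 0.00518 against 0.00499 in the simulations. The 2 single knockouts shared 4 calls (1.17 with divided controls), with 2 in opposite directions and a covariance of 0.00874 against 0.00497. Kdm5b, Foxa3, Gdf11 and Slc38a2 stood between wild type and double knockout in the Hdac2 knockout, with Foxa3 at 4.88, 6.98 and 8.96 and Gdf11 at 5.44, 7.23 and 10.05 in wild type, Hdac2 knockout and double knockout.

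**Figure D4:**
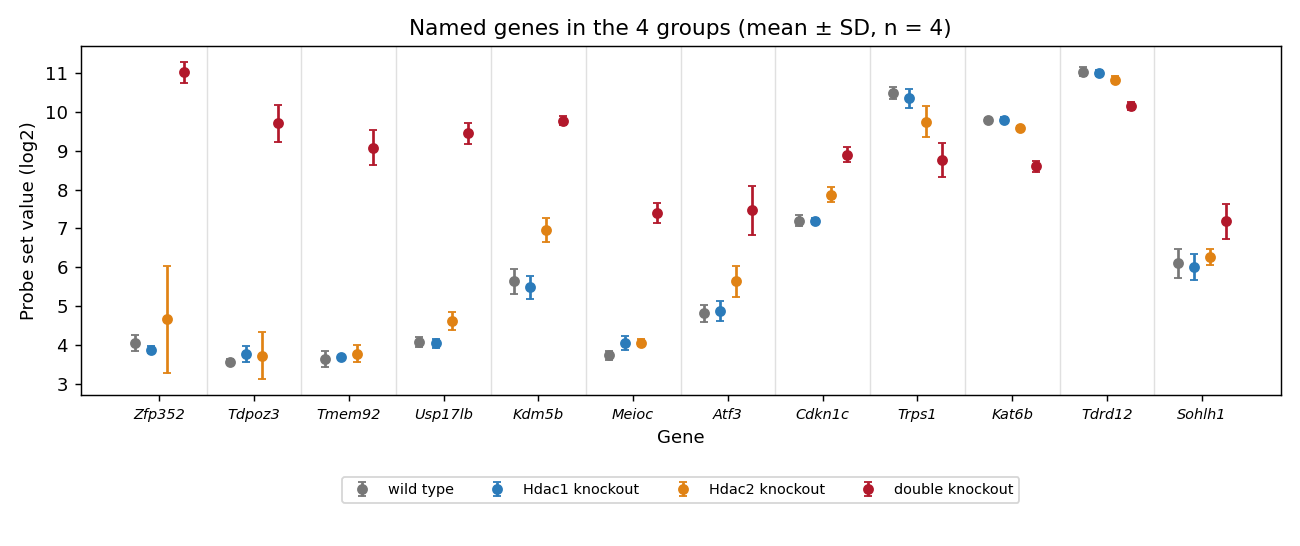
Mean probe set value (log2) of 12 named genes in the 4 groups, with bars giving the SD of 4 arrays. Kdm5b averages 5.64 in wild type, 5.48 in the Hdac1 knockout, 6.96 in the Hdac2 knockout and 9.77 in the double knockout, and Tdrd12 falls from 11.03 in wild type to 10.15 in the double knockout.

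Against the Hdac1 knockout, the double knockout differed in 8220 probe sets, 3964 higher and 4256 lower. The comparison was set to read loss of Hdac2 when Hdac1 is already lost, but Hdac1 was also 2.06-fold higher in the double knockout, so the groups do not differ in Hdac2 alone. Median-centring gave 3066 higher and 6238 lower, and quantile normalization 3464 and 5095. Zfp352 was 141-fold higher (7.14 ± 0.43 SE). Ccdc149 differed by -2.04 ± 0.19 and Bhlhe41, a circadian repressor, by -1.79, and Pramel27 by -3.69 ± 1.01 (limma adjusted p = 0.00739), or by -4.62 without Hdac1-knockout replicate 3. Stk36 differed by -1.90 ± 0.71 (limma adjusted p = 0.0445), a call lost in 6 of the 8 fits without 1 array. Oxidative phosphorylation genes (46 higher, 1 lower, 28 not passing; 52 and 1 adjusted over the list alone; camera adjusted p = 6.37e-09), ribosomal proteins (41, 2 and 29; 42 and 2; 4.07e-07) and 2-cell stage genes (10, 2 and 3; 10 and 3; 4.07e-07) were higher as groups, with adjusted p = 0.399, 0.447 and 0.172 with an estimated correlation. Cyclin-dependent kinase inhibitors (7, 0 and 1; 7 and 1; camera adjusted p = 5.93e-05) and core histones (12, 3 and 15; 12 and 3; 0.0418) were also called, with adjusted p = 0.0481 and 0.399 with an estimated correlation. Median, mean and test differed in sign for H3K4 methyltransferase complexes, blood markers, meiotic prophase genes and both apoptosis lists, which were not called.

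Against the Hdac2 knockout, the double knockout differed in 7155 probe sets, 3566 higher and 3589 lower. It was set to read loss of Hdac1 when Hdac2 is already lost, but it also holds the 108 calls that set the Hdac2 knockout apart from all other groups, Extl1 among them. With median-centring 2734 probe sets were higher and 4941 lower in the double knockout, and with quantile normalization 3087 and 4227. Zfp352 was 82.5-fold higher and Kdm5b 7.04-fold higher (limma adjusted p = 1.28e-08 and 2.91e-09), and without Hdac2-knockout replicate 2 the log2 change of Zfp352 went from 6.37 to 7.04. Pramel27 differed by -4.70 ± 1.01 (SE), Tceanc2 by -2.70 ± 0.60 and Extl1 by -2.47 ± 0.11. Called lists were oxidative phosphorylation genes (45 higher, 2 lower, 28 not passing; 50 and 3 adjusted over the list alone; camera adjusted p = 1.27e-08), ribosomal proteins (38, 1 and 33; 41 and 1; 7.94e-08), 2-cell stage genes (10, 2 and 3; 10 and 2; 1.98e-07) and cyclin-dependent kinase inhibitors (7, 0 and 1; 7 and 0; 0.000127), all upward. With an estimated correlation their adjusted p = 0.441, 0.441, 0.139 and 0.063. At the edge of the test, p53 targets were called upward (14, 6 and 13; 14 and 6) and piRNA genes downward (4, 12 and 5; 4 and 13), each at a camera adjusted p of 0.0499, with adjusted p = 0.139 and 0.216 with an estimated correlation. Median, mean and test differed in sign for meiotic prophase, oocyte growth and anti-apoptotic genes, H3K4 methyltransferase complexes and polymerase II factors, which were not called.

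The single knockouts differed from each other in 1226 probe sets, 597 higher and 629 lower in the Hdac1 knockout; the majority turned to 649 and 547 with median-centring and 668 and 585 with quantile normalization. Besides Hdac1 (-3.03), Rnase6 (-4.34 ± 0.50 SE), the amino acid transporter Slc7a8 (-2.36 ± 0.28), Hmgn3 (-2.33 ± 0.09) and Extl1 (-2.42 ± 0.11) were lower in the Hdac1 knockout. Crybg1 was higher by 1.20, Slc5a8 by 1.13 and Cmtm8 by 1.25 ± 0.32, the last (limma adjusted p = 0.0315) lost in 7 of the 8 fits without 1 array. Cyclin-dependent kinase inhibitors (0 higher, 1 lower, 7 not passing; 0 and 4 adjusted over the list alone; camera adjusted p = 0.0215) and H3K4 demethylases (0, 1 and 7; 0 and 2; 0.0436) were lower in the Hdac1 knockout, with adjusted p = 0.29 and 0.541 with an estimated correlation. Median, mean and test differed in sign for 10 lists, none of them called: deacetylases, DNA methylation machinery, p53 targets, both apoptosis lists, piRNA genes, polymerase II factors, ribosomal proteins, and granulosa and blood markers. The count was 794 and 785 without Hdac1-knockout replicates 1 and 3, and 752 and 678 without Hdac2-knockout replicates 1 and 4.

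The interaction asked whether the double knockout departed from the sum of the single-knockout changes, and it passed for 4939 probe sets, 2479 above the sum and 2460 below, against 2030 and 3005 with median-centring and 2208 and 2909 with quantile normalization. Zfp352 exceeded the sum by 6.54 ± 0.61 (SE), Rfpl4b by 6.09 ± 0.27, Tdpoz3 by 5.79 ± 0.35, Tmem92 by 5.25 ± 0.24 and Grp by 5.16 ± 0.22, and Kdm5b did so by 2.97 ± 0.24. Apart from Kdm5b, these genes lay near the lower end of the scale in wild type, as did 2-cell stage genes (median 4.40). A floor of signal can hide rises in the single knockouts there, so the size of such departures is uncertain. Mt1 lay below the sum by -4.62 ± 0.13, since its level was alike in the 3 knockouts, and Pramel27 by -5.99 ± 1.43, Tceanc2 by -3.58 ± 0.85, Manba by -4.59 ± 1.48 and Stk36 by -3.25 ± 1.01. Left-out arrays moved Zfp352 to 7.21 (Hdac2-knockout replicate 2), Pramel27 to -6.91 (Hdac1-knockout replicate 3) and -5.19 (wild-type replicate 2), Tceanc2 to -4.30 (Hdac1-knockout replicate 1), Manba to -5.60 (wild-type replicate 2) and Stk36 to -3.86 (Hdac2-knockout replicate 1). Single arrays also decided the calls for Manba and Stk36, which were lost in 12 and 7 of the 16 fits without 1 array. Hdac1 exceeded the sum by 0.68 ± 0.12 (limma adjusted p = 0.000539). Above the sum as groups were 2-cell stage genes (10 higher, 1 lower, 4 not passing; 10 and 2 adjusted over the list alone; camera adjusted p = 1.51e-08), cyclin-dependent kinase inhibitors (6, 0 and 2; 7 and 0; 0.000312), oxidative phosphorylation genes (34, 2 and 39; 36 and 2; 1.21e-07) and ribosomal proteins (26, 0 and 46; 29 and 1; 4.11e-06). With an estimated correlation their adjusted p = 0.107, 0.088, 0.556 and 0.644. The p53 targets were not called (camera adjusted p = 0.0558), but passed with median-centring (0.0322), with the replicate block (0.0457) and without wild-type replicate 1 (0.0448), Hdac2-knockout replicate 1 (0.0387) or double-knockout replicates 2 (0.0296) or 3 (0.0464). Median, mean and test differed in sign for oocyte growth, meiotic prophase and anti-apoptotic genes and for blood markers, which were not called.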

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

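The tests of the explanations for the 3 patterns in this part were chosen only after the results were seen, while the comparisons with other divisions of the arrays were planned.

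Mt1 rose by 4.63, 4.55 and 4.56 on the log2 scale in the Hdac1, Hdac2 and double knockouts. A metal or stress response would be expected to raise Mt2 too, and the highest upper bound of its change in the single knockouts was 0.052, which argues against that explanation there; Mt2 rose by 0.52 in the double knockout, where a part of this kind stays open, and at 4.93 in wild type it is dim. The lowest Mt1 change under other scalings was 4.47. Those scalings moved the median change by at most -0.09, in the double knockout, so the Mt1 change could not have fallen far. This shows only that array-wide shifts of that size are too small to give the Mt1 rise. An Mt1 sequence carried with the Cre transgene would give like levels in all 3 knockouts, and their differences were bounded at 0.26, so this may be the source. The transgene sequence was not examined, and a response to loss of either deacetylase stays open.

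Of 108 calls that set the Hdac2 knockout apart from the other 3 groups, 31 lay on chromosome 4, that of Hdac1 (28.7% against 5.99% of tested probe sets; Fisher's exact test, adjusted p = 2.33e-12), while of all calls in this knockout 7.85% did (adjusted p = 0.168). The 108 held 6 of the 9 called neighbours of Hdac1 (2 of the 9 are probe sets of Khdrbs1) and 102 of 1176 other calls. For those 6, sequence around Hdac1 that differs between these mice and the other groups could be the source. The rest of the 31 lay beyond the 50 genes on either side of Hdac1, and their distance from it was not examined. For the 9 neighbours as a group, though not for each of them, loss of Hdac2 itself is argued against as the cause. Of them 22.2% changed in the same direction in the double knockout against 79.1% of the other calls (Fisher's exact p = 0.000455). The 2 that did, named after their values were seen, were S100pbp (0.28 in the Hdac2 and 0.59 in the double knockout) and Zbtb8os (-0.59 and -0.31). This test and the count of 6 use the same arrays, so they are not independent. In the Hdac1 knockout, 5 of 13 calls lay on chromosome 10, that of Hdac2 (Fisher's exact p = 0.000201, or 0.00421 adjusted over all chromosomes), with 4 of the 6 calls that set this knockout apart, and 0 of 59 neighbours within 50 genes of Hdac2 but 2 of 98 within 100 (planned; adjusted p = 0.00478), which argues against chance placement. Flanking sequence of the modified alleles could be the source on both chromosomes only if the wild-type mice also carried those alleles. Each single knockout stood apart on the chromosome of the other gene, not around its own. Around its own gene, the Hdac1 knockout had 0 of 50 neighbours called and the Hdac2 knockout 2 of 59. Neither the alleles of the wild-type mice nor the flanking sequence was examined, and the labels give 1 strain background for all groups.

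Hdac1 was 2.06-fold higher in the double knockout than in the Hdac1 knockout. The rise of Hdac1 seen in the Hdac2 knockout, whose cause was not tested, cannot account for all of it. Hdac1 exceeded the sum of the single changes by 0.68 ± 0.12 (SE). Undeleted oocytes at a share of 19.8% could produce it, and then no gene could fall below -2.33. With 0 probe sets below that floor by over 2 standard errors, and a lowest change of -2.40 for Pramel27, this could not be told apart from other sources.

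With the 8 arrays of each comparison divided in all 35 ways, 1 division called as many probe sets as the real one in every case, namely the real one itself: 15 (highest other 2) for the Hdac1 knockout, 1187 (2) for the Hdac2 knockout, 8122 (0) for the double knockout, 8220 (0) and 7155 (1) for the double knockout against the Hdac1 and Hdac2 knockouts, and 1226 (2) between the single knockouts. For the interaction, 4939 probe sets compared with at most 3610 in other divisions among 100 drawn. For called lists, 20 of 35 divisions reached the 1 list of the Hdac1 knockout (highest other 3) and 8 of 35 the 3 lists of the Hdac2 knockout (highest other 5), so chance is not excluded there. The 8 lists of the double knockout were reached by 1 of 35 (highest other 7). Mixed divisions put genotype differences into the spread within groups, which lowers the calls of changed probe sets. The counts of other divisions are therefore no measure of false calls, and 1 of 35 is the most that this comparison could show.

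Single arrays lay far from the other 3 of their group in 29 cases among 310 groups of 4 tested, and chance gives about 1 in 20 groups. In wild type these were Poglut2 (6.88; others 7.01 to 7.03), Slc38a2 (4.81; 5.34 to 5.44), Nr5a2 (9.73; 9.84 to 9.85) and Manba (7.90; 3.83 to 3.88) in replicate 2, Styk1 (7.95; 8.16 to 8.19) in replicate 1 and Tdrd12 (11.20; 10.96 to 10.98) in replicate 3. The Hdac1 knockout had Hdac2 (11.05; 11.14 to 11.16) and Tdpoz3 (4.08; 3.64 to 3.70) in replicate 2, Enpp3 (4.42; 4.76 to 4.82) in replicate 1, Pramel27 (5.84; 9.36 to 9.77) and Manba (3.84; 7.49 to 7.79) in replicate 3 and Cmtm8 (6.07; 7.05 to 7.13) in replicate 4. For the Hdac2 knockout they were Hivep2 (5.65; 4.95 to 5.06) in replicate 3, Ednrb (5.06; 4.69 to 4.75) and Tdpoz3 (4.63; 3.41 to 3.43) in replicate 2, Pramel27 (9.98; 9.46 to 9.55) in replicate 4 and Stk36 (6.66; 9.07 to 9.12) in replicate 1. Double-knockout replicate 1 gave Zfp352 (10.61; 11.14 to 11.16), Tdpoz3 (9.001; 9.90 to 9.98), Pramel17 (7.85; 8.47 to 8.59), Ddx4 (10.90; 10.77 to 10.79) and Manba (7.95; 4.11 to 4.25). Replicate 2 of that group gave Cdk9 (8.48; 8.65 to 8.66). Replicate 3 gave Tdpoz8 (7.22; 8.74 to 8.94), Ccdc149 (4.87; 5.91 to 6.00), Dnmt3l (5.41; 6.29 to 6.37), Tdrd12 (9.99; 10.19 to 10.22), Gja1 (6.83; 6.23 to 6.28) and Bhlhe41 (5.85; 6.56 to 6.62).

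Departures from the sum of the single-knockout changes passed for 4939 probe sets, with Zfp352 at 6.54, Rfpl4b at 6.09, Tdpoz3 at 5.79, Tmem92 at 5.25, Grp at 5.16 and Kdm5b at 2.97. Those below the sum were Pramel27 (-5.99), Mt1 (-4.62), Manba (-4.59), Tceanc2 (-3.58) and Stk36 (-3.25). List medians were 2.01 for 2-cell stage genes, 0.53 for cyclin-dependent kinase inhibitors, 0.22 for oxidative phosphorylation genes and 0.16 for ribosomal proteins. For genes near the floor of signal in wild type, the size of these departures is uncertain.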

How the results depend on the processing

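The neighbour windows of 20 and 100 genes were planned, and the tests over whole chromosomes were chosen only after the results were seen. Adding an offset before taking logs was not applicable, since the deposited values are already on a log scale. The values carry no detection calls or background, so signal over background limits what a low value can show. Of 166 gene results, 13 changed in label under some alternative, 11 of them besides leaving out an array, and 0 reversed; the cause was not tested. Leaving out dim probe sets gave 24 changed in the Hdac1 knockout. At 1.4-fold or more, 454, 3472, 3518, 2576, 469 and 2685 probe sets remained for the Hdac2 and double knockouts, the double against the Hdac1 and Hdac2 knockouts, the single knockouts and the interaction, and the SAM-type test gave 490, 3489, 3536, 2619 and 520 for the first 5. Without 1 array at a time, with fewer arrays in the test, counts ran from 10 to 30 for the Hdac1 knockout, 683 to 952 for the Hdac2 knockout and 678 to 1242 between the single knockouts, the Hdac1 change in the Hdac2 knockout from 0.32 to 0.40, and the lists called in the Hdac1 knockout from 0 to 2. With an estimated correlation 0, 0 and 1 lists were called in the Hdac1, Hdac2 and double knockouts. With divided controls, and so fewer arrays per comparison, the overlaps averaged 335.8, 6 and 1.17, out of 452, 9.17 and 9.17 calls in the first knockout of each pair. Wider and narrower windows gave an adjusted p of 0.00478 around Hdac2 in the Hdac1 knockout (100 genes) and 0.0305 around Hdac2 in the double knockout (20 genes). With the replicate number as a block the counts were 12, 950, 7885, 8072, 6893, 1026 and 4667, with 1, 3 and 8 lists. Residuals showed no pairing by replicate number, with correlations from -0.148 to 0.0866 over 24 pairs. In 5 of these pairs an array matched best to its own number. Whether the numbers mark a batch or litter is not settled by this. Other scalings moved the median change by at most -0.09, in the double knockout.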

Other observations

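These groupings of genes were chosen only after the results were seen.

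Probe sets that rose at least 4-fold in the double knockout were mostly dim in wild type. Of 183 such probe sets, 128 lay below the median of tested probe sets (5.27) in wild type. In the Hdac2 knockout 60 of the 183 also rose, against 606 of all 21218 tested. Both comparisons use the same 4 wild-type arrays, which raises such sharing. At 2-fold or more, 347 of 604 lay below it. Of 285 at least 2-fold lower, 2 lay below that median; with a floor of signal, dim genes cannot show large falls. Pramel genes are a family of leucine-rich repeat proteins with close copies that share probe sequence. Of its 14 genes, 6 were at least 2-fold higher, against 2.94% of all tested genes. Fisher's exact test, here one-sided, gave an adjusted p of 0.000457 over 297 families. Falls were tested and adjusted separately. The 6 higher genes included Pramel17 (5.03), Pramel19 (4.05) and Pramel7 (2.86) on the log2 scale, while Pramel15 fell by 1.07.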
